A study of Bos taurus with 8 samples.

How the data were processed

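Cells that the labels give as primary bovine Müller glia, kept in culture for 18 to 21 days, were left untreated (2 arrays) or treated for 24 h with TAT at 100 ng/ml (3 arrays) or gp120 at 60 ng/ml (3 arrays). RNA of each sample was labelled with 1 dye and read on 1 array of an Agilent bovine design (029411), all 8 arrays on 1 slide. The labels carry replicate letters, A and B for the controls and A, B and C for the treated groups. The extraction text speaks of astrocytes, and which cells were measured was not tested. The labels do not say whether letters mark separate cultures or animals. The treatment text, which is the same for all samples, controls included, names TAT and gp120 together. It can also be read as both given at once, and the groups here follow the sample titles alone.

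The scanner files hold intensity values that, per the file headers, the authors made with Agilent Feature Extraction 11.5.1.1 (protocol GE1_1105_Oct12), which subtracted background and detrended each array and put surrogate values in place of spots near background. They are not scaled between arrays. The deposited value table holds log2 values per gene name, and how it was made is not given in the sources used here. Its column medians, in the order control A and B, TAT A, B and C and gp120 A, B and C, were -3.2, -3.3, -3.26, -3.21, -3.25, -3.25, -3.18 and -3.33. After a shift per array, 98% and 97.8% of its values for gp120 B and gp120 C lay within 0.02 of the scanner values, but only 8.5% to 15.2% for the other 6 arrays (r of 0.9934 to 0.9945). Scale and direction of the table follow from these comparisons, and no centring per gene was found. Which processing gave the values of the 6 arrays stays unknown, so the scanner files were used and the table served as an alternative.

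Processed signals were log2 transformed and each array's 75th percentile was subtracted. Control spots and spots flagged as outliers (4 to 37 per array) were left out, and repeated spots of a probe were averaged. Saturated spots numbered 0 on every array. Of 51282 probes, 31591 were kept as well above background on every array of at least 1 group, and 31546 had no missing value. Probes were named by accession (29884), symbol (5523) or synonym (149) against the bovine reference gene table, 580 kept the name in the file and 15146 stayed unnamed. Probe positions are those of the build in the file headers, HGSC Btau_3.1, and no genome was used. For the 7145 genes with more than 1 probe the brightest probe was taken, which left 12232 genes. Kept probes with no gene name (7131) were fitted but not counted as genes.

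Spots well above background made up 55.46% to 64.62% of each array. Row 1 of the slide held control A, TAT A, gp120 A and control B, and row 2 the other 4 arrays. gp120 B and gp120 C were read in another scan (scan 1) than the other 6 (scan 2), with a detector voltage of 471 in place of 431. Row and scan are therefore partly confounded with treatment, and both were tried as blocks. Within row 1 each protein has 1 array, and within scan 2 gp120 has 1 array (gp120 A), so shifts of a protein with 1 array there cannot separate batch from array or letter.

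Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, all arrays in 1 fit without a block, Benjamini-Hochberg over genes, two-sided, threshold 0.05) for TAT minus control, gp120 minus control, TAT minus gp120 and the mean of both proteins minus control. Gene lists (36, written before the files were seen) were tested with camera at a preset correlation between genes of 0.01, with an estimated correlation beside it, and with fry, which finds only movement in 1 direction. All p-values of genes and lists come from these limma functions. Other tools were statmod 1.5.0, data.table (1.17.8), Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

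The rule for named genes was fixed in advance. It takes the genes past the threshold whose arrays do not overlap between groups, with places up to 4 per direction filled by the smallest p-values, the 4 members with the smallest p of each list that passed, and a fixed set of inflammatory, glial and barrier genes. An "at least" bound replaces the value where a whole group is not well above background. It sets the mean of the bright group against the dim group at its own signal or the lowest signal well above background on that array, whichever is higher. It is a bound for background alone, holds for the main processing only and leaves out the spread between arrays. Some genes that the rule picks are not reported here.

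The letters were checked for pairing before the fits were compared. Between arrays of different groups, deviations from the group means correlated at 0.372 to 0.74 with the same letter and at -0.65 to 0.415 with different letters. These ranges overlap. With 2 controls the deviations of control A and control B are mirror images, so this measure cannot place control B. It gave 0.402 with TAT B and 0.415 with TAT C. By the SD of the difference between arrays control B lay closest to TAT B (0.436) and gp120 B (0.603), with TAT C at 0.641. On both measures together the letters were taken to pair the arrays. Letter C has no control, so shifts of a treated group against control without the block also hold differences between letters. Gene values and list shifts come from the fit without the block unless stated. That fit counts differences between letters as spread, and its median SE for TAT minus control was 0.311, against 0.227 with the block. The fit with the letters as a block is given where it changes a call or a count.

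The fit was tested on simulated data with known changes, in 5 runs per comparison. The simulated arrays held the letter differences and the residual spread of the fit with the block. Better recovery with the block was therefore built in. Without the block, changes of 1, 2 and 3 on the log2 scale were recovered in 2.3%, 57.5% and 80.8% of genes for TAT minus control, 1.2%, 59.1% and 84.5% for gp120 minus control, and 4.5%, 67.2% and 87.3% for TAT minus gp120, with 0%, 0.8% and 0% of calls false. With the block the recovered shares were 36%, 96.9% and 98.2%, 31.3%, 95.4% and 99.4%, and 61.3%, 98.6% and 99.7%, with 4.9%, 7.3% and 6.1% false. In 20 simulated runs without any change camera called 1 list at the preset correlation and 0 with the estimated one. The noise of each gene was drawn independently there. These runs therefore cannot test the preset correlation for lists whose genes move together.

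Alternatives written before the files were seen (26) changed the normalization, background correction, filter, variance model, probes, threshold, block, source of values and replicates. A further 13 were added after the data were seen, mostly for scan and slide row.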

Results

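Cells given as primary bovine Müller glia, although the extraction text speaks of astrocytes, were treated for 24 h with the HIV-1 proteins TAT (100 ng/ml, 3 arrays) or gp120 (60 ng/ml, 3 arrays). They were compared with 2 control arrays, and the groups are those of the sample titles. The question was which genes each protein changes and whether the 2 proteins act alike. Of 12232 genes tested with limma, 0 passed an adjusted p of 0.05 in any of the 4 comparisons, without and with the replicate letters as a block. The results are therefore shifts of whole gene lists and values of single genes that did not pass. The labels do not say whether replicates are separate cultures or animals, so the p-values measure only the spread between these samples.

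The arrays grouped by replicate letter (A, B, C) rather than by protein. The first component held 50.7% of the variance and placed the 3 letter A arrays apart from all others, and the second, with 18.5%, parted letter B from letter C. Between letters 1742 genes differed past an adjusted p of 0.05 with the group in the fit, and 4067 at an unadjusted p under 0.05. Letter C has no control array, so shifts against control without the block also hold differences between letters.

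**Figure D1:**
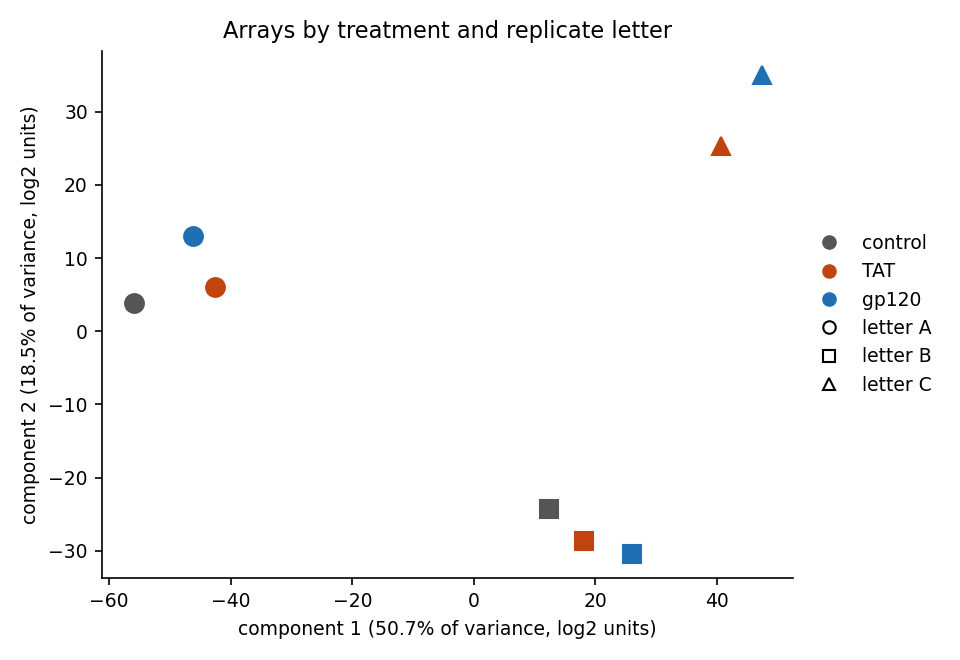
The 8 arrays on the first 2 principal components of the tested genes (axes in log2 units, 50.7% and 18.5% of the variance), coloured by treatment, with the marker shape giving the replicate letter. The arrays of each letter lie together whatever their treatment.

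With TAT, genes of the extracellular matrix were higher than in control. All 28 measured members of the matrix list were higher, by a mean of 0.70 on the log2 scale, with a camera adjusted p of 3.38e-21 and adjusted p = 0.148 with an estimated correlation. The collagen chains COL1A1 (0.92, SE 0.29), COL12A1 (0.72, SE 0.29) and COL1A2 (0.54, SE 0.24) and the microfibril protein FBN1 (0.76, SE 0.28) had the smallest p-values on the list. Of 13 fibroblast and stromal markers 12 were higher, by a mean of 0.65 (adjusted p = 2.72e-07, and adjusted p = 0.148 with an estimated correlation). Among them PRRX1, a transcription factor of mesenchyme, was 0.81 higher (SE 0.30), but on only 1 of its 2 probes. LUM, a proteoglycan that spaces collagen fibrils, was 1.62 higher (SE 0.90). Without single arrays COL12A1 went from 0.308 to 1.133 and LUM from 0.809 to 2.326. Without TAT A the stromal shift was 0.35 (adjusted p = 0.00588, over 20 settings 6.38e-12 to 0.00588). Row 1 holds both controls but only TAT A of the TAT arrays, and TAT A has the highest matrix level. The shifts within row 1, 1.04 and 1.27, are therefore of 1 array, and with slide row as a block they were 0.77 and 0.94. All control and TAT arrays were read in scan 2, so scan as a block and that scan alone repeat the same comparison (0.70 and 0.65). The matrix shift was 1.21 from control A to TAT A and 0.21 from control B to TAT B.

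Interferon-stimulated genes were lower with TAT in 35 of 38 cases, by a mean of -0.42 (adjusted p = 7.25e-05, and adjusted p = 0.721 with an estimated correlation). The virion tether BST2 stood at -0.74 (SE 0.37), the ubiquitin ligase HERC6 at -0.56 (SE 0.34) and the antiviral GTPase MX2 at -0.47 (SE 0.29). The shift depended on single arrays. Without control A the camera mean shift was 0.03 (adjusted p = 0.626), a setting that leaves only a letter B control, and it was -0.86 without control B, -0.65 without TAT A and -0.26 without TAT B. Within letters it was -0.41 in A and -0.29 in B, and with the letters as a block and without control A -0.20, with 31 of 38 genes lower (adjusted p = 0.161). With slide row as a block it was -0.15 (adjusted p = 0.398) and within row 1, where only TAT A is left, 0.04 (adjusted p = 0.89). Over 20 other settings the adjusted p went from 2.93e-08 to 0.89. Scan as a block and scan 2 alone keep all control and TAT arrays, so they repeat the same comparison, with a shift of -0.42.

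Further lists were higher with TAT. The complement list had a mean of 0.46, with 15 of 19 genes above 0 (adjusted p = 7.25e-05, and adjusted p = 0.442 with an estimated correlation). It held the serine proteases of the classical pathway C1R (1.34, SE 0.65) and C1S (1.15, SE 0.58) and their substrate C4A (0.69, SE 0.34). Angiogenic and neurotrophic factors had a mean of 0.40, with 21 of 24 above 0 (adjusted p = 7.25e-05, and adjusted p = 0.148 with an estimated correlation). Among them were the vessel-destabilising ligand ANGPT2 (0.72, SE 0.38), the lipase inhibitor ANGPTL4 (0.89, SE 0.52), the lymphangiogenic VEGFD (0.71, SE 0.45) and the growth factor IGF1 (1.37, SE 0.87). Notch and Wnt genes had a mean of 0.32, with 20 of 24 above 0 (adjusted p = 0.00276, and adjusted p = 0.191 with an estimated correlation). The Wnt co-receptor LRP5 stood at 0.57 (SE 0.23), the secreted DKK3 and SFRP4 at 0.56 (SE 0.25) and 0.90 (SE 0.57), and the ligand WNT2B at 1.49 (SE 0.75). With slide row as a block the complement shift was 0.46 (adjusted p = 0.00069), the angiogenic shift 0.12 (adjusted p = 0.088) and the Notch and Wnt shift 0.15 (adjusted p = 0.0689). Within row 1 they were 0.46, 0.17 and 0.25 for TAT A alone, and within scan 2 they were 0.46, 0.37 and 0.34. Within letters A and B the complement shift was 0.33 and 0.38, the angiogenic shift 0.34 and 0.32 and the Notch and Wnt shift 0.46 and 0.14. The complement list no longer passed without control B (0.32, adjusted p = 0.145). Without control A the angiogenic shift was 0.21, and the Notch and Wnt list no longer passed (0.16, adjusted p = 0.248), while it was 0.52 without control B and 0.60 without TAT A. With the letters as a block and without control A the complement, angiogenic and Notch and Wnt shifts were 0.29, 0.34 and 0.40, and all 3 passed, with adjusted p = 0.717 with an estimated correlation.

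The cell cycle list had a mean of 0.33, with 31 of 35 genes above 0 (adjusted p = 2.06e-04, and adjusted p = 0.727 with an estimated correlation). Pericyte and smooth muscle markers had a mean of 0.49, with 10 of 11 above 0 (adjusted p = 0.00892, and adjusted p = 0.721 with an estimated correlation). Junction genes had a mean of 0.27, with 14 of 19 above 0 (adjusted p = 0.024, and adjusted p = 0.721 with an estimated correlation). The replication genes MCM3, CDC6, MCM5 and CDC45 were 0.31 to 0.78 higher and the contractile and mural genes MCAM, ACTA2, PDGFRB and TAGLN 0.37 to 0.75 higher. The adhesion genes CTNNB1, JAM3, NECTIN2 and CDH11 were 0.54 to 0.70 higher, although CTNNB1 was higher on only 1 of its 4 probes. Within letters A and B the cell cycle shift was 0.27 and -0.06, the pericyte shift 0.75 and 0.18 and the junction shift 0.51 and -0.09. All 3 calls were lost without control A, where only a letter B control is left and the shifts were -0.20, -0.49 and -0.05. With the letters as a block and without control A the shifts were 0.13, 0.14 and 0.10, and 0 of the 3 passed (adjusted p of 0.068, 0.16 and 0.796). Without control B and with no block they were 0.83, 1.39 and 0.54. The cell cycle shift was 0.64 without TAT A and lost its call without TAT C (0.10, adjusted p = 0.109). The pericyte shift was 0.83 without TAT A and lost its call without TAT B (0.19, adjusted p = 0.127), and the junction list lost its call without TAT A (adjusted p = 0.133). With slide row as a block the cell cycle list turned to -0.39 (adjusted p = 0.0101), and the pericyte and junction shifts of -0.25 and 0.07 gave adjusted p of 0.998 and 0.348. Within row 1, for TAT A alone, the 3 shifts were -0.23, -0.15 and 0.37, and within scan 2 they were 0.33, 0.49 and 0.28. With the replicate letters as a block 14 of the 36 lists passed in place of 9. The added lists were TGF-beta targets, ribosomal proteins and retinal neuron markers (higher) and oxidative phosphorylation and lysosomal genes (lower). With an estimated correlation 0 lists passed in either fit, and fry called 0 lists too. When the 5 control and TAT arrays were regrouped so that other pairs stood for the control, 4 to 14 lists passed, and 4 to 10 where the pair held 1 letter A and 1 letter B array as the real one does.

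No single gene passed for TAT. Limma's adjusted p was 1 for each gene, and 149 genes had an unadjusted p under 0.05 (478 with the letters as a block) where chance would give 612. In this and the other comparisons the fit without the block counts letter differences as spread. Its numbers below chance are therefore not evidence of fewer changes than chance. As over all genes, 0 members of any list passed when adjusted over the list alone, and with the letters as a block 1 cytokine did. The 95% interval of a change reached 0.72 to either side in the median gene, and 0.54 with the letters as a block. The arrays of the 2 groups did not overlap for 14.22% of genes, where chance gives 20% for exchangeable arrays, which arrays paired by letter are not. Among these the smallest p-values belonged to MIR1296 (a microRNA gene), at least 5.46-fold higher, the lipase LIPE, at least 1.99-fold higher, the corepressor RCOR1, at least 1.69-fold higher, and the orphan receptor GPR21, 0.79 higher on the log2 scale (SE 0.23). For the first 3 the bound equals the fitted log2 difference (2.45, 1 and 0.75), so it is no margin for the spread between arrays. Without single arrays the fitted differences of these 3 were as low as 2.02, 0.53 and 0.56. With normexp background correction LIPE and RCOR1 turned to -0.12 and -0.10. Over all settings MIR1296 was as low as 0.029 and GPR21 as low as 0.516, so the bounds hold for the main processing only. On the lower side stood the olfactory receptor OR10G9F, at least 2.85-fold lower, the neurotensin receptor NTSR2, at least 2.86-fold lower, the sarcomere protein MYBPC1, at least 4.37-fold lower, and the transition protein TNP1, with -1.36 (SE 0.28). Over all settings the log2 differences of OR10G9F, NTSR2, MYBPC1 and TNP1 came as near to 0 as -0.134, -0.316, -0.356 and -0.34.

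Inflammatory and glial genes chosen in advance gave no call with TAT (adjusted p of 1 each). The chemokines CCL2 and CXCL8 had log2 changes of -0.42 (SE 0.80) and -1.27 (SE 1.55), and the cytokines IL6, TNF and IL1B had 0.66 (SE 1.69), -0.81 (SE 0.78) and -0.33 (SE 1.41). The adhesion molecule ICAM1 stood at 0.18 (SE 0.33), the intermediate filament VIM at -0.02 (SE 0.26), glutamine synthetase GLUL at -0.27 (SE 0.30) and the glutamate transporter SLC1A3 at -0.27 (SE 0.54, lower on 1 of its 2 probes). VEGFA, the vessel growth factor, stood at 0.01 (SE 0.21), the gelatinases MMP2 and MMP9 at 0.36 (SE 0.35) and -0.24 (SE 0.33), the junction protein TJP1 at 0.28 (SE 0.31) and heme oxygenase HMOX1 at -0.20 (SE 0.40). GFAP and RLBP1, markers of glia, and CCNT1, the cyclin that TAT binds, were not tested because their best probes were well above background on only 2, 2 and 4 of the 8 arrays. Of 28 listed Müller glia genes 19 were well above background on all 8 arrays, near the share over all genes (11168 of 17283). So were 21 of 22 microglia and macrophage markers and 12 of 14 fibroblast and stromal markers. SOX9 of the Müller glia list was read from probes of SOX10. KCNJ10, SLC1A2 and CA14 of that list were well above background on 1, 1 and 0 arrays. The Müller glia count therefore does not mark the cells as Müller glia. The mix of cells was not tested, so the shifts cannot be given to Müller glia alone.

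With gp120, interferon-stimulated genes and cytokines were lower than in control. Interferon-stimulated genes were lower in 33 of 38 cases, by a mean of -0.48 (adjusted p = 2.18e-04, and adjusted p = 0.845 with an estimated correlation). The smallest p-values belonged to the antiviral proteins SAMD9 (-1.23, SE 0.33), IFIT2 (-1.67, SE 0.59) and RSAD2 (-2.35, SE 0.95) and the RNA sensor DDX58 (-1.17, SE 0.36, lower on 1 of its 2 probes). Without single arrays IFIT2 went from -2.676 to -0.654 and RSAD2 from -3.533 to -1.159. Cytokines and chemokines were lower in 20 of 21 cases, by a mean of -0.76 (adjusted p = 0.00737, and adjusted p = 0.845 with an estimated correlation). The lowest p-values belonged to IL15 (-1.29, SE 0.37), IL18 (-0.97, SE 0.41), the interferon-induced chemokine CXCL10 (-0.83, SE 0.49) and the neutrophil attractant CXCL8 (-2.14, SE 1.55). Without control A, where only a letter B control is left, the interferon shift was -0.04 (adjusted p = 0.935) and the cytokine shift -0.01 (adjusted p = 0.929), and without control B they were -0.93 and -1.50. With the letters as a block and without control A the interferon shift was -0.26 (26 of 38 lower, adjusted p = 0.206). The cytokine shift was then -0.72 (18 of 21 lower, adjusted p = 1.17e-04, and adjusted p = 0.978 with an estimated correlation). The cytokine shift was -1.22 without gp120 A and lost its call without gp120 B (-0.52, adjusted p = 0.131). Within letters the interferon shift was -0.85 in A and -0.17 in B, and the cytokine shift -0.60 in A and -0.50 in B. Of the gp120 arrays only gp120 A lies in scan 2 and in row 1, so values with scan as a block, within scan 2 and within row 1 all set that 1 array against controls of both letters. They were -0.40 in each for the interferon list and 0.15, 0.22 and 0.16 for cytokines, which are high in letter A. With the letters and scan as blocks together the cytokine call held (-0.82, adjusted p = 3.23e-07), and over 20 settings its adjusted p went from 6.04e-08 to 0.994. The interferon and cytokine shifts were -0.21 (adjusted p = 0.203) and 0.44 (adjusted p = 0.0913) with slide row as a block. With the replicate letters as a block 4 cytokines and 3 interferon-stimulated genes passed when adjusted over the list alone, as did 1 gene of the Notch and Wnt list, and 0 over all genes; without the block 0 passed either way.

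Among lists that were higher with gp120 were the cell cycle list (30 of 35 genes, mean 0.42, adjusted p = 2.18e-04, and adjusted p = 0.845 with an estimated correlation) and the matrix list (24 of 28, mean 0.26, adjusted p = 0.00189, and adjusted p = 0.845 with an estimated correlation). Also higher were ribosomal proteins (41 of 59, mean 0.11, adjusted p = 0.0105, and adjusted p = 0.884 with an estimated correlation) and complement (15 of 19, mean 0.34, adjusted p = 0.0195, and adjusted p = 0.845 with an estimated correlation). CDC6, MCM3, MCM5 and MCM6, which license and unwind replication origins, were 0.40 to 0.77 higher. FBN1 was 0.70 higher (SE 0.28), COL1A1 0.62 (SE 0.29), the collagen-binding SPARC 0.56 (SE 0.32) and the adhesion-modulating TNC 0.48 (SE 0.30). RPL11, RPL4, RPS2 and RPL13 were 0.26 to 0.41 higher, and the complement genes CFI, CD59, C1QC and C1S 0.71 to 1.40 higher. RPL4 was higher on 4 of its 5 probes and RPL13 on 3 of its 5, with a median over the RPL13 probes of 0.04. With gp120 A as the only gp120 array (scan as a block, within scan 2 or within row 1) the cell cycle shift was -0.46, and letter A is low in cell cycle genes. In these settings the matrix shift was 0.07, the ribosomal shift -0.05 and the complement shift 0.34. The 4 shifts, in the order cell cycle, matrix, ribosomal and complement, were -0.30, 0.34, 0.06 and 0.34 with slide row as a block. Within letters A and B the cell cycle shift was 0.05 and 0.42, the matrix shift 0.24 and 0.27, the ribosomal shift -0.34 and 0.66 and the complement shift 0.20 and 0.09. Single arrays mattered for all 4 calls. Without control A the cell cycle and matrix calls were lost (-0.12 and 0.10) and the ribosomal shift was 0.40. With the letters as a block and without control A the cell cycle shift was 0.20 (adjusted p = 0.0202, and adjusted p = 0.978 with an estimated correlation), the matrix shift 0.02 (adjusted p = 0.785), the ribosomal shift 0.56 and the complement shift 0.18 (adjusted p = 0.206). With no block and without control B the ribosomal and complement calls were lost (-0.19 and 0.21) while the cell cycle and matrix shifts were 0.93 and 0.43. Without gp120 A the cell cycle shift was 0.89, the ribosomal shift 0.18 and the complement call lost (0.35, adjusted p = 0.235). Without gp120 B the cell cycle, matrix and ribosomal calls were lost (0.17, 0.16 and -0.03) and the complement shift was 0.54, and without gp120 C the cell cycle shift was 0.24 and the complement call lost (0.15). The complement call held in 14 of 20 settings, with adjusted p from 3.27e-04 to 0.405.

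No single gene passed for gp120. Limma's lowest adjusted p was 0.999, and 302 genes had an unadjusted p under 0.05 where chance would give 612. With the letters as a block the lowest adjusted p was 0.394, and 634 genes (5.18%) had an unadjusted p under 0.05. Whether that number exceeds chance was not tested. Of all genes 13.32% had arrays that did not overlap where chance gives 20% for exchangeable arrays, which arrays paired by letter are not. The smallest p-values among those belonged to the membrane protein SYPL2 (1.01, SE 0.25), the integrator subunit INTS4 (1.54, SE 0.40, higher on 1 of its 2 probes), the Golgi protein GOLGA1 (0.82, SE 0.22) and RCOR1, at least 1.83-fold higher. For RCOR1 the bound equals the fitted log2 difference (0.87), which was as low as 0.68 without single arrays. Over all settings the lowest log2 differences of SYPL2, INTS4, GOLGA1 and RCOR1 were 0.017, 0.146, 0.189 and 0.028. On the lower side stood OR10G9F, at least 2.68-fold lower, the receptor kinase FLT3, at least 3.02-fold lower (but a log2 difference of 4.75 within row 1 alone, where another probe stands for the gene), WDR64, at least 2.15-fold lower, and the metalloprotease MMP24 (-1.15, SE 0.26). Over all settings OR10G9F, WDR64 and MMP24 came as near to 0 as -0.198, -0.197 and -0.174. With an estimated correlation and with fry 0 lists passed, and regrouping the 5 control and gp120 arrays gave 4 to 17 lists, and 4 to 5 with 1 letter A and 1 letter B array as the control pair, where the real groups gave 6.

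Among the genes chosen in advance CCL2 stood at -0.61 with gp120 (SE 0.80), IL6 at -0.47 (SE 1.69), TNF at -0.67 (SE 0.78), IL1B at -1.05 (SE 1.41) and ICAM1 at 0.46 (SE 0.33), with an adjusted p of 0.999 for each. VIM, GLUL, SLC1A3, MMP2, MMP9, TJP1 and HMOX1 lay between -0.09 and 0.13, and VEGFA at -0.21 (SE 0.21). Only 1 of 5 MMP2 probes and 1 of 3 MMP9 probes had the sign of the value used, and the median over the MMP2 probes was 0.4.

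**Figure D2:**
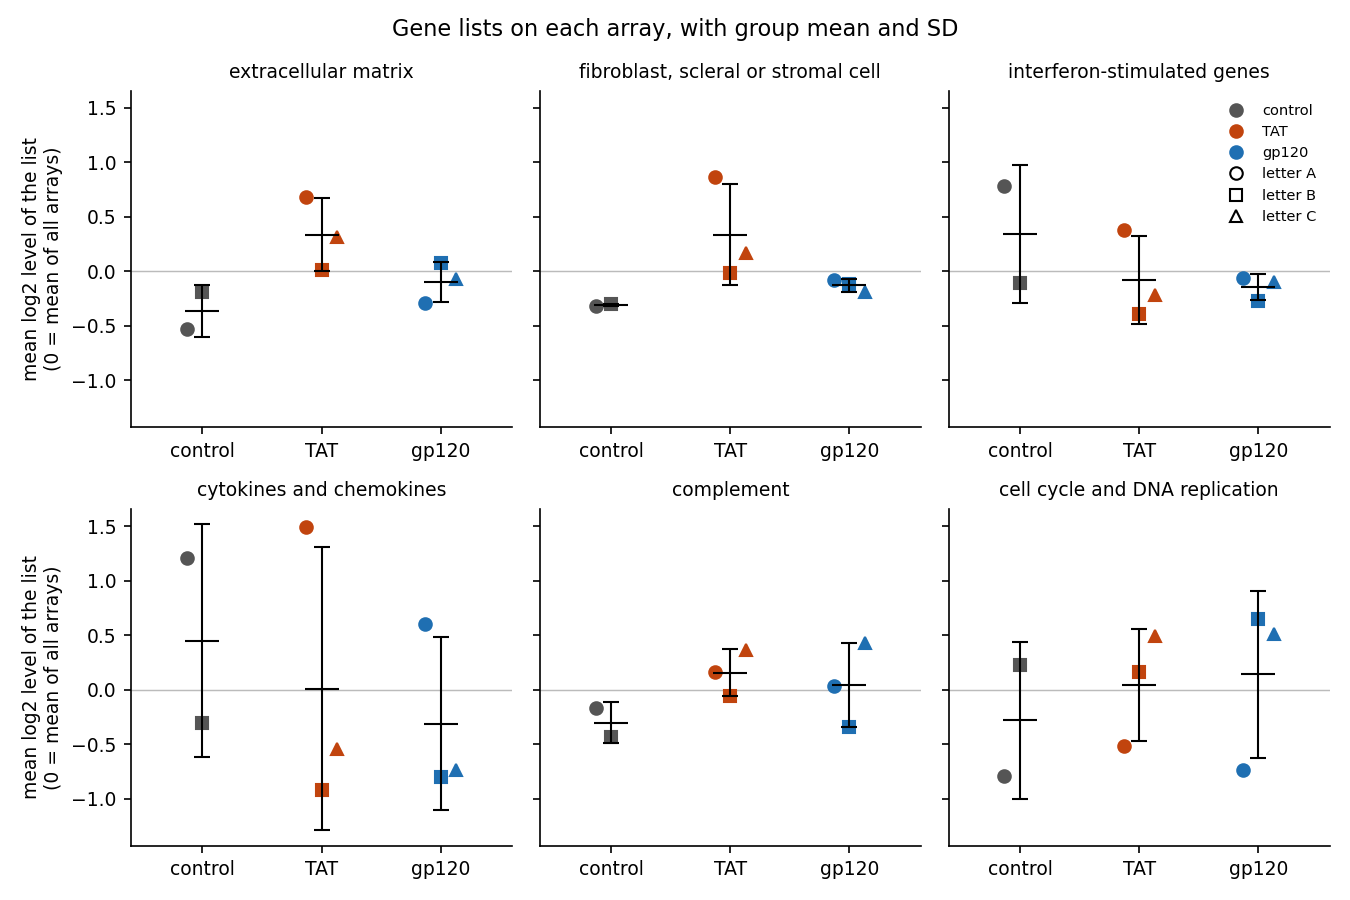
Mean log2 level of 6 gene lists on each array, centred on the mean of all 8 arrays, by treatment; points are arrays with the replicate letter as shape, and bars give the group mean and SD. The matrix list has its highest value on TAT A, and the interferon list its highest on control A.

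Between the 2 proteins, matrix and stromal genes were higher with TAT. The matrix list was higher in 26 of 28 genes by a mean of 0.43 (adjusted p = 1.07e-07, and adjusted p = 0.842 with an estimated correlation). The proteoglycan VCAN stood at 1.16 (SE 0.28), the basement membrane collagen COL4A2 at 0.88 (SE 0.26), COL5A2 at 0.75 (SE 0.30) and COL12A1 at 0.55 (SE 0.26). Stromal markers were higher in 11 of 13 cases by a mean of 0.47 (adjusted p = 0.00264, and adjusted p = 0.842 with an estimated correlation). PRRX1 stood at 1.04 (SE 0.26, higher on 1 of its 2 probes) and COL1A2 at 0.45 (SE 0.22). The matrix glycoprotein FBLN1 stood at 1.89 (SE 1.22, higher on 1 of its 2 probes) and the proteoglycan DCN at 0.60 (SE 0.43). The matrix difference was 0.97 between the letter A arrays, -0.06 between the letter B arrays and 0.39 between the letter C arrays. Without TAT A it was 0.23 (adjusted p = 0.0442). Within row 1, which holds 1 array of each protein, it was 0.97 and within row 2 0.12 (adjusted p = 0.517, over 21 settings 2.34e-20 to 0.517). With slide row as a block it was 0.43, and with scan as a block or within scan 2, where gp120 A is the only gp120 array, 0.63. The stromal call was lost without TAT A (0.13, adjusted p = 0.339) and without gp120 A (0.49, adjusted p = 0.0997). The stromal difference was 0.97 within row 1, 0.12 within row 2 (adjusted p = 0.572), 0.47 with slide row as a block and 0.42 with scan as a block and within scan 2. With the replicate letters as a block 5 lists passed in place of 2, with cytokines and Notch and Wnt genes higher and lysosomal genes lower with TAT, and 0 passed with an estimated correlation. With that block 1 stromal marker and 1 TGF-beta target passed when adjusted over the list alone, and 0 without it.

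No single gene differed between the proteins past the threshold. Limma's lowest adjusted p was 1, and 285 genes had an unadjusted p under 0.05 where chance would give 612. With the letters as a block the lowest adjusted p was 0.695, and 865 genes (7.07%) had an unadjusted p under 0.05. Whether that number exceeds chance was not tested. Of all genes 6.61% had arrays that did not overlap where chance gives 10% for exchangeable arrays, which arrays paired by letter are not. Among those the zinc finger protein ZFP106 (1.42, SE 0.27, but -0.50 in the deposited value table), the collagen receptor subunit ITGA1 (1.19, SE 0.24) and the chromatin regulator ARID5B (1.02, SE 0.24) were higher with TAT. So was the transcription factor ARNT2, by at least 2.5-fold, but its log2 difference was as low as 0.097 over all settings. ZBTB9 (-0.86, SE 0.21, but as near to 0 as -0.064 without single arrays), the catenin ARVCF (-1.08, SE 0.26), TNP1 (-0.97, SE 0.25) and the homeobox gene HOXD4 (-0.82, SE 0.22) were lower with TAT.

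**Figure D3:**
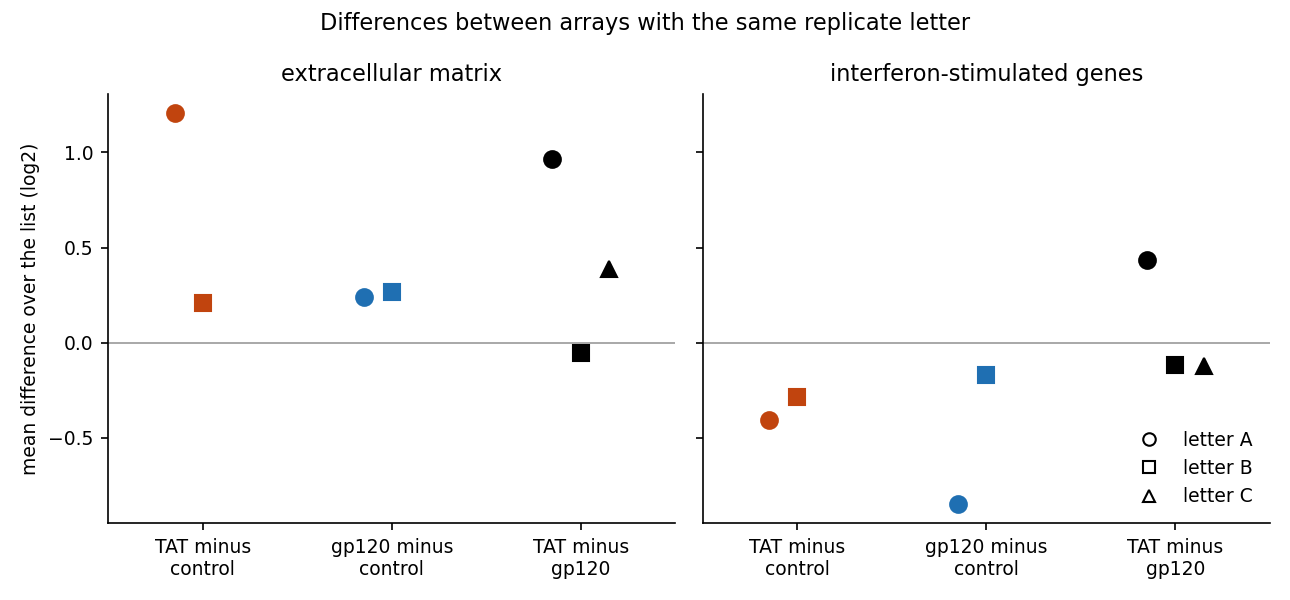
Mean log2 difference over the matrix list (left) and the interferon list (right) between arrays of the same replicate letter, for TAT minus control, gp120 minus control and TAT minus gp120. For TAT minus control the matrix difference is 1.21 in letter A and 0.21 in letter B.

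Taking both proteins against the controls, 13 lists passed, of which 10 were higher and 3 lower. Matrix genes were higher in 27 of 28 cases by a mean of 0.48 (adjusted p = 5.4e-12, and adjusted p = 0.419 with an estimated correlation). FBN1 stood at 0.73 (SE 0.25), COL1A1 at 0.77 (SE 0.26), TNC at 0.52 (SE 0.27) and the crosslinking enzyme LOXL2 at 0.68 (SE 0.37). Interferon-stimulated genes were lower in 34 of 38 cases by a mean of -0.45 (adjusted p = 1.06e-05, and adjusted p = 0.772 with an estimated correlation). DDX58 stood at -0.83 (SE 0.32, lower on 1 of its 2 probes), SAMD9 at -0.68 (SE 0.30), RSAD2 at -1.90 (SE 0.85) and IFIT2 at -1.19 (SE 0.53). Without single arrays RSAD2 went from -3.09 to -0.716 and IFIT2 from -2.197 to -0.174. Stromal markers (mean 0.41, adjusted p = 3.22e-04, and adjusted p = 0.419 with an estimated correlation) and complement (mean 0.40, adjusted p = 4.39e-04, and adjusted p = 0.583 with an estimated correlation) were higher in 12 of 13 and 14 of 19 genes. Row 1 sets TAT A and gp120 A against controls A and B, and scan 2 leaves gp120 A as the only gp120 array. The matrix shift was 0.56 with slide row as a block, 0.55 within row 1, 0.39 with scan as a block and 0.38 within scan 2. In the same order the stromal shift was 0.70, 0.79, 0.44 and 0.44, and the complement shift was 0.40 in each. The matrix shift was 0.31 without control A, and the complement call was lost without control B (0.27, adjusted p = 0.238). The interferon shift was -0.18 with slide row as a block (adjusted p = 0.226) and within row 1 (adjusted p = 0.0577), -0.41 with scan as a block (adjusted p = 2.89e-06) and within scan 2, -0.004 (adjusted p = 0.894) without control A and -0.90 without control B.

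Another 9 lists passed for both proteins. Cytokines were lower in 18 of 21 genes by a mean of -0.60 (adjusted p = 0.0098, and adjusted p = 0.823 with an estimated correlation), with IL15, CXCL10, IL18 and CCL8 at -0.75 to -1.13. The list turned to 0.60 with slide row as a block and 0.68 within row 1 (-0.14 with scan as a block and -0.12 within scan 2). It was -0.56 with the letters as a block and without control A (16 of 21 lower, adjusted p = 0.00213, and adjusted p = 0.886 with an estimated correlation). With no block it lost its call without control A (0.15) and without TAT B (-0.37), and was -1.38 without control B and -0.97 without TAT A. Cell cycle genes were higher by 0.38 (adjusted p = 2.64e-05, and adjusted p = 0.823 with an estimated correlation), with MCM3, CDC6, MCM5 and RRM2 at 0.51 to 0.74. The list turned to -0.34 with slide row as a block and within row 1 (-0.06 with scan as a block and within scan 2). It was 0.16 with the letters as a block and without control A (adjusted p = 0.0265, and adjusted p = 0.886 with an estimated correlation). With no block it lost its call without control A (-0.16), and was 0.88 without control B, 0.62 without gp120 A and 0.25 without gp120 B. Apoptosis and p53 targets were lower by -0.20 (adjusted p = 0.0479, and adjusted p = 0.772 with an estimated correlation). Among them were the p53 target ZMAT3 (-0.66, SE 0.23), the survival factor BCL2 (-0.66, SE 0.27), the decoy receptor TNFRSF10D (-0.78, SE 0.34) and the apoptosome subunit APAF1 (-0.38, SE 0.22, lower on 1 of its 2 probes). TNFRSF10D was lower on 3 of its 4 probes, with a median over them of -0.21. The list shift was -0.03 with slide row as a block and -0.08 with scan as a block, and its call was lost without control A (-0.11), control B (-0.30), TAT B (-0.18), gp120 B (-0.16) or gp120 C (-0.18). Antigen presentation (mean 0.24, adjusted p = 0.0479, and adjusted p = 0.823 with an estimated correlation) and angiogenic factors (mean 0.30, adjusted p = 0.00162, and adjusted p = 0.419 with an estimated correlation) were higher. So were junction genes (mean 0.29, adjusted p = 0.0288, and adjusted p = 0.772 with an estimated correlation) and pericyte markers (mean 0.38, adjusted p = 0.0157, and adjusted p = 0.823 with an estimated correlation). Notch and Wnt genes (mean 0.21, adjusted p = 0.0462, and adjusted p = 0.583 with an estimated correlation) and ribosomal proteins (mean 0.07, adjusted p = 0.0274, and adjusted p = 0.896 with an estimated correlation) were higher. Of these 6 lists antigen presentation and angiogenic factors passed with scan as a block (0.36 and 0.15), and 0 passed with slide row as a block, while within row 1 antigen presentation passed (0.30, adjusted p = 0.0406).

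Leaving out single arrays, with no block unless stated, moved these 6 lists for both proteins too. Without control A the angiogenic, junction, pericyte and Notch and Wnt calls were lost (0.11, -0.05, -0.60 and 0.07), and the antigen presentation and ribosomal shifts were 0.49 and 0.37. With the letters as a block and without control A the angiogenic and ribosomal lists passed (0.24 and 0.52, adjusted p = 0.886 with an estimated correlation), and the junction, pericyte, Notch and Wnt and antigen presentation shifts of 0.10, 0.03, 0.31 and 0.16 did not. Without control B antigen presentation was lost (-0.001), ribosomal proteins turned to -0.22, and the angiogenic, junction, pericyte and Notch and Wnt shifts were 0.49, 0.56, 1.28 and 0.41. Without TAT A the antigen presentation, junction and ribosomal calls were lost (0.27, 0.30 and 0.05) and the Notch and Wnt shift was 0.43. Without TAT B antigen presentation, ribosomal proteins, Notch and Wnt genes and pericyte markers were lost (0.23, 0.06, 0.19 and 0.23), and without TAT C antigen presentation (0.22). Without gp120 A antigen presentation was lost (0.18), and the ribosomal, Notch and Wnt and pericyte shifts were 0.11, 0.58 and 0.59. Without gp120 B the junction, ribosomal, Notch and Wnt and pericyte calls were lost (0.19, 0.003, 0.14 and 0.18) and antigen presentation was 0.41, and without gp120 C antigen presentation was lost (0.13). With the replicate letters as a block antigen presentation and the apoptosis list no longer passed (adjusted p = 0.412 and 0.051), and 4 cytokines and 1 gene of the Notch and Wnt list passed when adjusted over the list alone, against 0 without the block.

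No single gene passed for both proteins together. Limma's lowest adjusted p was 0.999, and 183 genes had an unadjusted p under 0.05 (472 with the letters as a block, lowest adjusted p 0.51) where chance would give 612. Of all genes 4.84% had arrays that did not overlap where chance gives 7.14% for exchangeable arrays, which arrays paired by letter are not. OR10G9F had the smallest p (fitted value -1.89, SE 0.31, unadjusted p = 3.47e-04). It was not well above background on any array of either treated group, so this value is not exact, and over all settings it came as near to 0 as -0.238. On the lower side MMP24, FLT3 and the olfactory receptor OR9G10 followed, and on the higher side stood MIR1296, RCOR1, LIPE and INTS4.

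The responses to TAT and to gp120 were correlated across genes, which are not independent replicates, with a Pearson r of 0.705, a Spearman rho of 0.646 and a covariance of 0.12. Both share the 2 controls. Simulated arrays with no effect of either protein gave an r of 0.599 (SD 0.014) and a covariance of 0.122 when the arrays were independent, and an r of 0.746 and a covariance of 0.0797 when the letter differences were kept. With control A used for TAT and control B for gp120 r was -0.14, and the other way round -0.103. In these splits the 2 responses share no control array. Each is set against a control of 1 letter, so differences between letters enter both values. Across letters, with a separate control for each, TAT A minus control A against gp120 B minus control B gave 0.105, and TAT B minus control B against gp120 A minus control A gave -0.156. The response to the same protein in letters A and B had an r of -0.03 for TAT and -0.042 for gp120. The correlation was 0.566 with the letters as a block, 0.741 with slide row as a block, 0.516 within row 1, 0.059 with scan as a block and 0.04 within scan 2, the last 3 with gp120 A as the only gp120 array. With 0 calls in both comparisons the overlap of called genes was 0.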

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

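The matrix list stood 0.433 higher and the stromal list 0.466 higher (mean log2) with TAT than with gp120. Both were singled out because the 2 proteins differed in a direct camera test of TAT minus gp120, and not by setting a passing result beside a failing one. Both have adjusted p = 0.842 with an estimated correlation, and fry called 0 lists.

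The mean net signal of the negative control spots was 19.89 on gp120 B and 17.834 on gp120 C, against 9.844 and 9.866 on the control arrays. These values were singled out because they lie above the controls on the 2 arrays of the separate scan, a part of the files that the comparisons do not use.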

How the results depend on the processing

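Counts of genes. Without and with the replicate letters as a block limma called 0 genes in all 4 comparisons. With the block, lists with a member passing when adjusted over the list alone went from 0 to 1 for TAT, 3 for gp120, 2 for TAT minus gp120 and 2 for both. It ended the calls of antigen presentation and apoptosis genes for both proteins, and it added pericyte markers for gp120 and matrix proteases, TGF-beta targets and oxidative phosphorylation for both. With the deposited values 4 genes passed for TAT, 4 for gp120, 16 for TAT minus gp120 and 1 for both proteins. With these values and the replicate block 4 genes passed for TAT, 3 genes for gp120 and 15 genes for TAT minus gp120. All calls with these values and without the block come from genes with several probes, with a scanner change under 1, and in 4, 4, 15 and 1 of them the table combined the probes differently in different groups. SP1, for example, stood at -3.18 in the table and at -0.04 in the scanner files. At an unadjusted p under 0.05 with a change of at least 1, 52, 118, 80 and 49 genes passed. Within scan 2, where gp120 A is the only gp120 array, 4 genes passed for gp120, all higher (C8H8orf74, CHST3, GBA3 and OVOL2, named after their values were seen), and 7 for TAT minus gp120, all lower. Leaving out 1 array at a time gave 0 to 16 genes for TAT, 0 to 7 for gp120, 0 to 1 for TAT minus gp120 and 0 to 14 for both.

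Counts of lists. For TAT 9 lists became 14 with the block and 0 with an estimated correlation, and 9 to 14 without single arrays. For gp120 6 became 0 with an estimated correlation and 4 to 7 without single arrays. For TAT minus gp120 2 became 5 with the block, 0 with an estimated correlation, 9 with scan as a block, 8 within scan 2, 11 within scan 2 with the block, 10 within row 1, 10 with the block and scan, and 2 to 6 without single arrays. For both proteins 13 became 0 with an estimated correlation, 7 with scan as a block, 8 within scan 2, and 7 to 14 without single arrays.

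Reversed lists. The cell cycle list for TAT turned from 0.327 to -0.393 with slide row as a block. For gp120 it turned from 0.423 to -0.456 with scan as a block, -0.456 within scan 2 and -0.456 within row 1, which are 1 and the same comparison of gp120 A with the 2 controls. Ribosomal proteins for gp120 turned from 0.107 to -0.197 within scan 2 with the block. For both proteins cytokines turned from -0.601 to 0.597 with slide row as a block and 0.676 within row 1, the cell cycle list from 0.375 to -0.345 with slide row as a block and -0.345 within row 1, and ribosomal proteins from 0.074 to -0.218 without control B (0.369 without control A). The cause of these turns was not tested.

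Of 632 alternative values of the 30 list calls, 458 kept the call, 164 lost it and 10 reversed it. The matrix and stromal calls for TAT and for both proteins held in the 20 settings with the preset correlation listed here. For a protein against control some settings keep all arrays compared, such as leaving out an array of the other protein. For TAT the scan settings do so too. Such settings repeat nearly the same shift, so the counts of kept calls overstate how far they were tested. With the letters as a block and without control A together, the stromal list for both proteins no longer passed (0.236, adjusted p = 0.0998). Of 4943 alternative values of 177 named gene results 4368 stayed the same, 575 moved and 223 had the other sign. Settings that repeat nearly the same comparison are among these too. Among named list members, CDH11, VEGFD, IGF1, CDC6, CDC45, MCAM and TAGLN for TAT turned in 1 to 3 settings each. For gp120 CD59, C1S, CXCL8, MCM3, MCM5, MCM6, CDC6, RPL4, RPS2 and RPL13 turned in 2 to 5 settings each, all of which involve scan or slide row. FBLN1 for TAT minus gp120 turned without TAT A (-0.316) and within row 2 (-0.216).

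Correlation of the responses. From 0.705 it moved to 0.683 with normexp background correction, 0.611 without a filter, 0.669 with probes above background on all 8 arrays, 0.566 with the block, 0.741 with slide row as a block, 0.059 with scan as a block, 0.04 within scan 2, 0.298 within scan 2 with the block, 0.516 within row 1 and 0.343 with the block and scan. Separate controls gave -0.14 and -0.103, matched letters across letters 0.105 and -0.156, and within a letter, where the control is shared, 0.601 and 0.421. Without single arrays it was 0.478 to 0.9.

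The alternatives with scan, with single rows, with matched letters, with the letters as a random effect (consensus correlation 0.467), and with the block joined to the table or to an intensity trend were chosen after seeing the data.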

Other observations

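The largest differences between these cultures follow the replicate letter, a pattern that the comparisons of the 2 proteins do not ask about. These tests were chosen after the result was seen. Letter A arrays carried more cytokine transcripts (19 of 21 genes, median log2 1.59, adjusted p = 5.98e-08, and adjusted p = 0.69 with an estimated correlation) and fewer cell cycle transcripts (2 of 35 genes higher, median -0.92, adjusted p = 1.19e-10, and adjusted p = 0.791 with an estimated correlation) than letters B and C. Pericyte and smooth muscle markers were lower in letter A as well (1 of 11 higher, median -1.115, adjusted p = 6.19e-04, and adjusted p = 0.69 with an estimated correlation), and whether the letters differ in cell composition was not tested. The acute-phase gene SAA3 was lower by -3.81 in B and -3.84 in C than in A, while the myosin light chain MYL4 was 4.77 and 3.15 higher and the radial glia lipid carrier FABP7 2.94 and 3.77 higher.

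Letter C lacked 7 genes that all other arrays expressed (DEFB123, PTPRR, KLK12, NXPH1, BOLA-DQA5, LOC518526 and PRSS2), with gaps of 4.8 to 7.18 on the log2 scale. No gene was absent from a whole treatment group with a gap of at least 4. These genes were picked after their values were seen.

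Arrays grouped by replicate letter. Control B lay closer to the letter B arrays of the other slide row (largest SD of the difference 0.603) than to any letter A array of its own row (smallest 0.721), which speaks against slide row. gp120 C lay closer to TAT C of the other scan (0.478) than to gp120 B of its own scan (0.712), which speaks against scan. Letters may mark separate animals or cell preparations, and 7 genes off in a whole letter were counted, but of 280 groupings 9 others reach the same 7 because they keep letter C whole, so this test cannot tell. Groupings that keep no letter whole reach 0.

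Interferon-stimulated genes lower with both proteins. The shift may come from control A alone, a prediction written before the test: with the letters as a block and without control A it was -0.228 (adjusted p = 0.0998), which misses the threshold as predicted, but 27 of 38 genes were still lower. Within letter B it was -0.287 for TAT and -0.169 for gp120, so whether control A is the whole source stays open. Within row 1 it was -0.18 (adjusted p = 0.0577), which cannot settle the part of slide row, a test chosen after the result was seen like the next. Without the arrays of scan 1 it stayed at -0.409. All control and TAT arrays were read in the same scan, so the TAT part of the shift (-0.419) cannot come from scan. The gp120 part then rests on gp120 A alone, set against controls of both letters. For gp120 this test therefore cannot separate scan from array or letter, and scan stays open.

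Matrix genes higher with TAT. Without TAT A the camera shift was 0.513 (adjusted p = 4.86e-09 at the preset correlation), so a positive shift remains without that array. Control A then has no TAT array of its letter, and TAT C has no control. Between arrays of the same letter the shift was 1.207 in A and 0.208 in B. How much of the shift comes from TAT A therefore stays open. With slide row as a block it was 0.772, but row 1 holds TAT A as its only TAT array (1.038), so slide row stays open. A larger share of fibroblast-like cells could raise the list, a prediction written before the test: the 6 stromal markers outside the matrix list had a mean of 0.369 (SE 0.226, 5 of 6 above 0) against 0.698 for the matrix list, which cannot tell the 2 apart. The tests of TAT A and of slide row were chosen after the result was seen.

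Splits of the 6 treated arrays. All 10 of 10 splits into 3 and 3 called as many genes as the real one (real 0, highest other 1), and 10 of 10 as many lists (real 2, highest other 13). With 10 splits a share under 0.05 cannot be reached. A split that calls several times the real number of lists points to a structure of the samples. The 3 other splits that part all 3 letters, as the real one does, called 6 to 13 lists. Regrouped controls gave 4 to 14 lists for TAT (real 9) and 4 to 17 for gp120 (real 6), but most of these pairs hold other letters than the real one. The 3 other pairs with 1 letter A and 1 letter B array gave 4 to 10 lists for TAT and 4 to 5 for gp120. Their highest matrix shifts were 0.524 (real 0.698) and 0.064 (real 0.265), and their lowest interferon shifts -0.179 (real -0.419) and -0.343 (real -0.483). With so few pairs a share under 0.05 cannot be reached.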
